A study of Homo sapiens with 3 samples.

How the data were processed

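The study sorted gene-trap mutagenized HAP1 cells for low surface staining of a glycosylphosphatidylinositol (GPI)-anchored protein and read out where the gene trap had integrated. HAP1 is a near-haploid human cell line, so a single insertion can remove the only copy of a gene. The gene trap is a retroviral cassette that truncates a transcript when it lands in an intron in the sense orientation or in an exon. Per the labels' protocols, live cells were stained on ice with an antibody against CD59 or against the prion protein PrP and sorted for low surface levels. Genomic DNA was then extracted, the sequence next to each insertion was copied by linear PCR with a biotinylated primer, and the captured products received a linker and Illumina adapters by a further PCR.

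A single table was used, with 27984 genes and 3 libraries: a CD59 screen, a PrP screen and a control that the file header credits to an earlier publication. Per the submitters' processing notes, the tools were Bowtie 0.12.08 and bedtools 2.17.0 and the genome build was hg19. The gene models, the rule that turned reads into insertion sites and any filter on sites are not given in the sources used here. Per the file headers, the authors deposited for each library the count of sense intron insertions per gene and the count of inactivating insertions, which adds insertions in exons. These counts are whole numbers with no normalization. The authors also deposited, per the file headers, a p-value of Fisher's exact test for each screen, and the headers do not say whether it was adjusted. The table holds no positions, so no coordinates are given, and 26 gene names had been turned into dates by spreadsheet software and were kept as unnamed genes in totals and tests. Of the names, 19586 are current symbols in a RefSeq gene table (GRCh38.p14), 2360 are older names there and 6038 matched neither. Names are given as in the table.

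The groups follow the sample titles and descriptions, which go with the file headers. The antibody field of the labels names the other protein for each sorted sample, and the insertions in CD59 and PRNP were therefore examined before anything else. Each group holds 1 library. There is no replicate check, and every p-value compares libraries and covers counting error only. PCR products were collapsed to insertions by the authors in a way not described here, so the intervals do not cover amplification or sorting error.

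The measure was the number of inactivating insertions in a gene as a share of those in all genes of the library. Each screen was compared with control by Fisher's exact test per gene, one-sided for more insertions in the screen. The screens were compared with each other by the two-sided Fisher's exact test. P-values were adjusted by the Benjamini-Hochberg method over the genes with at least 1 insertion in either library, which were 22029 genes for CD59, 22023 for PrP and 6138 between the screens. A gene was called below an adjusted p of 0.05. Odds ratios are conditional estimates with exact 95% intervals, shares have exact Clopper-Pearson 95% intervals, and a count of 0 was taken to allow up to 3 insertions, library by library. Where a gene has 0 insertions in a library, the fold is the share in the other library over that limit. This bound leaves out the counting error of the other library, so the exact lower limit of the odds ratio is given beside it.

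The choices above, 26 gene lists and the rule for naming genes were fixed before the data were examined. The rule named CD59 and PRNP, the 20 called genes with the smallest p in each screen, the 10 with the smallest p in each direction between the screens, and every list member called. For each list the number of called members and the median log2 ratio of shares, with 0.5 added to each count, were set against 10000 random lists of equal size. Each member was replaced from the 200 genes nearest to it in control count, or in mean share of both screens for the comparison between them. All list members were found in the table.

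The tests were run on simulated libraries of the same totals, with 200 of 27984 genes raised by known folds. The raised genes were drawn from genes above a minimum control count, so the percentages do not cover genes with few control insertions. For the CD59 screen, 18.8% of genes raised 5-fold, 68.0% of those raised 20-fold and 99.6% of those raised 100-fold were called. For the PrP screen the values were 5.6%, 36.8% and 87.2%. Between the screens, 11.6% of genes changed 20-fold and 34.4% of those changed 100-fold were called.

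The alternatives were a minimum of 5 insertions, library totals without called genes, a two-sided test, Bonferroni adjustment, an exact test in edgeR with an assumed coefficient of variation of 0.4 and TMM factors, a threshold of 0.001 for the overlap, and other matching and pseudocounts for the lists. Added after the data were seen were sense intron insertions alone, a CD59 library thinned to the PrP total, library totals of the genes called in both screens, the edgeR exact test without TMM factors, the overlap of the genes edgeR called, and the authors' deposited p-values. Counts of all insertions, including antisense intron insertions, were not used here, so a test on them, chosen in advance, was not run. The tools were Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.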

Results

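Haploid genetic screens were used to compare the genes needed for surface display of 2 GPI-anchored proteins, CD59, a complement inhibitor, and PrP, the prion protein. The data are inactivating gene-trap insertions per gene in 3 libraries from HAP1 cells, with 1 library in each group. The CD59 screen held 11508 inactivating insertions in 5353 genes, the PrP screen held 3208 in 1824 genes, and the unsorted control held 2537384 in 22018 genes. A gene with 100 control insertions was expected to hold 0.454 insertions in the CD59 library and 0.126 in the PrP library if its share equalled that in control. At that control count, 6 insertions sufficed for a call in the CD59 screen and 4 in the PrP screen, which are enrichments of 13.2-fold and 31.6-fold. Smaller observed enrichments of such a gene could not be called at this depth.

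The genes that encode the sorted proteins were examined to check the labels. CD59 held 122 insertions in the CD59 screen, or 1.06% of the library (95% interval 0.881% to 1.26%), against 1 in the PrP screen and 50 in control, where its share was 0.00197%. PRNP, which encodes PrP, held 58 insertions in the PrP screen, or 1.81% (1.38% to 2.33%), against 0 of 11508 in the CD59 screen, which allows a share of up to 0.0261%, and 68 in control. The odds ratio of CD59 between the screens was 34.4 (6.05 to 1369), with an adjusted p of 9.52e-09 by Fisher's exact test. The share of PRNP was at least 69.4-fold higher in the PrP screen (exact lower limit of the odds ratio 55.6), with an adjusted p of 1.74e-35 by the same test. In the edgeR exact test with assumed variation PRNP passed with and without TMM factors, and CD59 passed with them (adjusted p 0.00585) and not without (0.286). The libraries thus go with the sample titles and against the antibody field of the labels, which names PrP for the CD59 screen and CD59 for the PrP screen.

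The first comparison asked which genes held more insertions in the library sorted for low surface CD59 than in control. The file header credits the control to an earlier publication. Effects of sorting were thus not separated from differences between libraries in mutagenized pool or preparation. In the CD59 screen 40 genes held more insertions than expected from control, and 24 of them belonged to the lists fixed in advance. These 40 genes held 2208 insertions, or 19.2% of the library. All 5 subunits of the GPI transamidase, which attaches the finished anchor to proteins, were called. GPAA1 held 132 insertions with an odds ratio of 491 (359 to 678), PIGT held 107 with 476 (337 to 681), PIGK held 82 with 467 (315 to 703), PIGS held 312 with 347 (289 to 416), and PIGU held 138 with 189 (149 to 239).

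Of the 14 genes for GlcNAc-PI synthesis and GPI mannosylation, 11 were called in the CD59 screen, a count reached by none of the random lists, which held at most 2. With matching on the mean share of the CD59 and control libraries, the random lists held at most 6. PIGA, PIGC, PIGH, PIGP and PIGQ, subunits of the enzyme that starts the pathway on phosphatidylinositol, held 15, 28, 19, 218 and 57 insertions. PIGL, the deacetylase of the next step, held 45 insertions, and PIGW, which acylates the inositol, held 28. In the edgeR exact test with assumed variation the calls of PIGL and PIGW ended with TMM factors (adjusted p 0.0718 and 0.300). Both were kept without them (0.0016 and 0.0109). The mannosyltransferases PIGM, PIGV and PIGB held 39, 89 and 144 insertions, and PIGX, the partner of PIGM, held 32. In this list the odds ratios ran from 21.6 (14.1 to 31.8) for PIGW to 387 (293 to 514) for PIGB. The remaining 3 genes were PIGY and PIGZ, with 0 insertions each, and DPM2, with 1. These 3 genes had 19, 20 and 72 control insertions. The median log2 ratio of the list was 6.31, above all random lists.

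Among the 4 genes of ethanolamine phosphate addition, PIGN, PIGO and PIGF were called, with 77, 122 and 19 insertions and odds ratios of 129 (95.7 to 172), 171 (134 to 218) and 68.8 (38.8 to 117). PIGG held 1 insertion, against 107 in control. Of the 13 genes that supply dolichol phosphate mannose, the mannose donor, 4 were called. PMM2, the phosphomannomutase, held 107 insertions with an odds ratio of 287 (213 to 387). DPM1 and DPM3, subunits of the donor synthase, held 37 and 59, and MPDU1, needed to use the donor, held 56. Of the 6 genes of anchor remodelling, PGAP2 was called, with 30 insertions against 1.04 expected and an odds ratio of 28.8 (19 to 42.3). In the edgeR exact test with assumed variation its call ended with TMM factors (adjusted p 0.0797) and was kept without them (0.00225). The other members, PGAP1, PGAP3, MPPE1, TMEM8A and TMEM8B, held 0 insertions each, with 0.145 to 0.522 expected.

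The largest adjusted p among the list members called in the CD59 screen was 7.46e-22, for PIGA, by the one-sided Fisher's exact test. Adjusted over the list alone, the called members were 11 for GlcNAc-PI synthesis and mannosylation, 3 for ethanolamine phosphate addition, 5 for the transamidase, 5 for dolichol phosphate mannose supply, with DOLK added at 2 insertions, and 1 for remodelling. Outside the lists and the sorted protein's gene, 15 genes were called. Of these, SPPL3, an intramembrane protease named after its values were seen, held 25 insertions with an odds ratio of 40.0 (25 to 61.6) and an adjusted p of 2.33e-27 by Fisher's exact test. The other 14 held 2 to 11 insertions each, and the test used does not cover differences between library preparations.

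**Figure D1:**
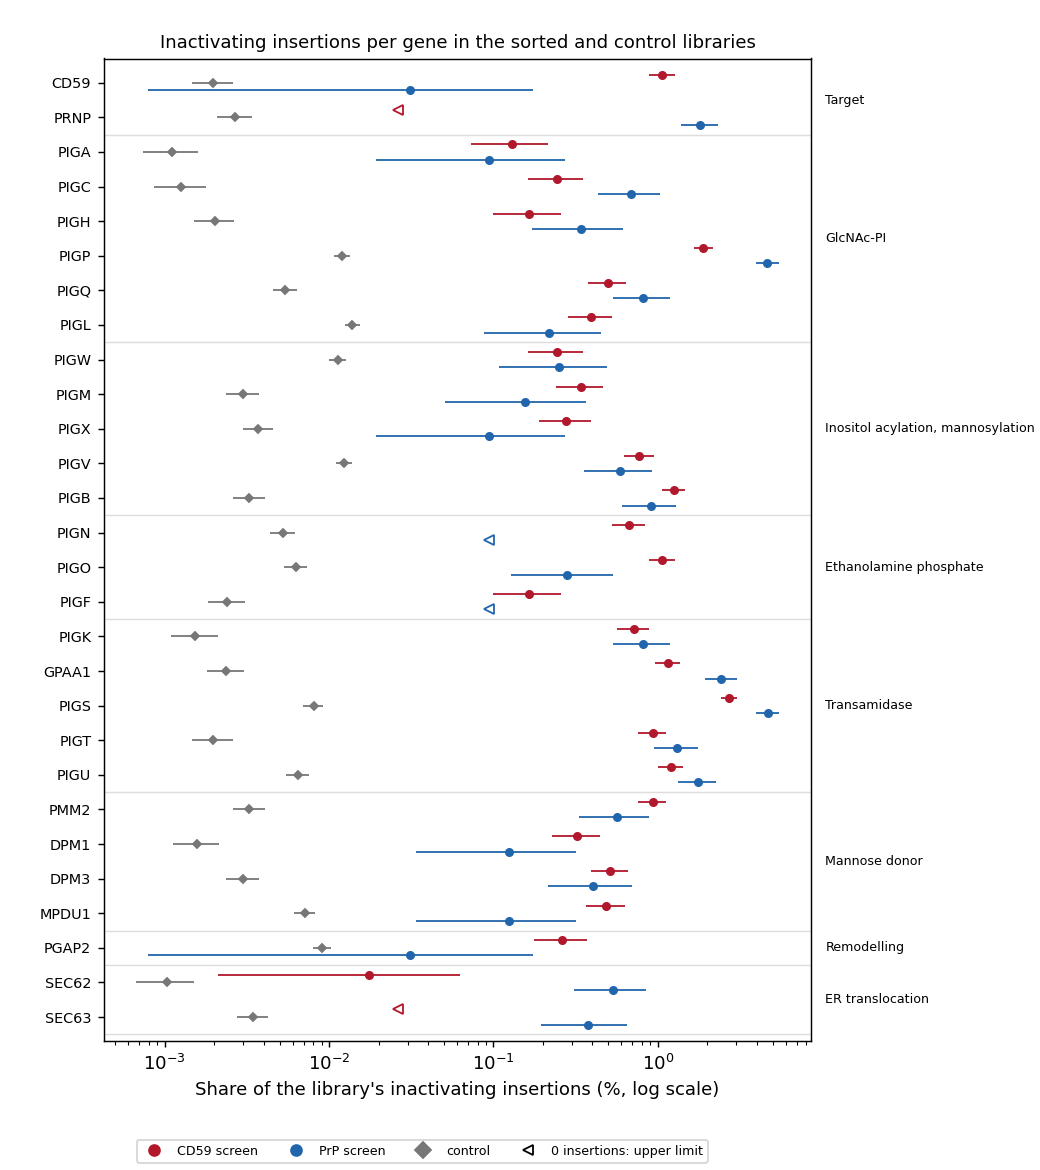
The share of each library's inactivating insertions (percent, log axis) is plotted for CD59, PRNP and the called list members, with exact 95% intervals, in the CD59 screen (red), the PrP screen (blue) and control (grey diamonds). Open triangles mark the limit that a count of 0 allows, which lies at 0.0935% for PIGN in the PrP screen, below the 0.669% of the CD59 screen.

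The same comparison was made for cells sorted for low surface PrP. In the PrP screen 29 genes were called, which held 792 insertions or 24.7% of the library, and 21 of them were list members. The transamidase list was again called in full, with 150 insertions in PIGS, 78 in GPAA1, 56 in PIGU, 42 in PIGT and 26 in PIGK. Their odds ratios ran from 277 (200 to 378) for PIGU to 1054 (741 to 1504) for GPAA1. Of the 14 genes of GlcNAc-PI synthesis and mannosylation, 10 were called. PIGP led with 149 insertions and an odds ratio of 408 (332 to 499), followed by PIGB with 29, PIGQ with 26, PIGC with 22, PIGV with 19, PIGH with 11, PIGW with 8, PIGL with 7, PIGM with 5 and PIGA with 3. In the edgeR exact test the calls of PIGW, PIGL, PIGM and PIGA ended with and without TMM factors, that of PIGV ended with them, and Bonferroni adjustment ended that of PIGA. PIGX held 3 insertions with an adjusted p of 0.157 by Fisher's exact test, and adjusted over the list alone it passed, for a total of 11.

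PIGO was the member of the ethanolamine phosphate list called in the PrP screen, with 9 insertions and an odds ratio of 44.9 (20.1 to 87.5). PIGN and PIGF held 0 of 3208 insertions, which allows a share of up to 0.0935%. Of the dolichol phosphate mannose list, PMM2, DPM3 and DPM1 were called, with 18, 13 and 4 insertions. In the edgeR exact test the call of DPM1 ended with TMM factors (adjusted p 0.546) and without them (0.661). MPDU1 held 4 insertions with an adjusted p of 0.0733 by Fisher's exact test, and passed when adjusted over the list alone, for a total of 4. No gene of anchor remodelling was called, and PGAP2 held 1 insertion with 0.291 expected.

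In the list of the endoplasmic reticulum (ER) translocation channel and its partners, SEC62 and SEC63 were called in the PrP screen. Both encode membrane proteins that assist the SEC61 channel in moving proteins into the ER. SEC62 held 17 insertions, with an odds ratio of 520 (264 to 996) and an adjusted p of 4.13e-35 by Fisher's exact test. SEC63 held 12, with an odds ratio of 109 (54.4 to 201) and an adjusted p of 1.85e-17 by the same test. No other of the 14 members passed, and the random lists held at most 1 called gene. Matched on the mean share of both libraries, random lists reached 2 called genes, and 98.6% held fewer. That matching is loose for SEC62, since few genes held as large a share of the PrP library. In the CD59 screen no member of this list was called, with 2 insertions in SEC62 and 0 in SEC63. The PrP library is 3.59 times shallower than the CD59 library, and 7 called genes outside the lists held only 2 to 7 insertions each.

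The other lists held no called gene in either screen. They were the GPI side chain and later-described GPI factors, p24 cargo receptors, COPII coat, signal recognition particle and receptor, signal peptidase, GET tail-anchor insertion, the ER membrane protein complex, oligosaccharyltransferase, lipid-linked oligosaccharide assembly, and glucosidases with the calnexin cycle. The rest were Golgi N-glycan processing, sialic acid and Golgi sugar transport, Golgi ion homeostasis with V-ATPase assembly, the COG, TRAPP, GARP with EARP and retromer complexes, ER-associated degradation, heparan sulfate assembly, and cytosolic ribosomal proteins. Adjusted over the list alone, TRAPPC12 in the CD59 screen with 3 insertions, RPL9 in the CD59 screen with 5 and ALG5 in the PrP screen with 2 passed. The p24 family includes receptors that carry GPI-anchored proteins out of the ER. The 10 genes of this list held 0 insertions in both screens, with 3.86 expected from control in the CD59 library and 1.07 in the PrP library. At these depths no depletion of a gene was called in either screen by the two-sided Fisher's exact test.

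The screens shared 19 called genes, all of them list members for GPI synthesis, the mannose donor or the transamidase. Independent lists of 40 and 29 genes among the 22018 tested in both would share 0.0527 genes. In 200 simulations of unchanged libraries set against the shared control, no gene was called in both. These values leave out, respectively, the shared control and the real effects, and the single control library cannot be split, so part of the overlap may come from it. A further 21 genes were called in the CD59 screen alone and 10 in the PrP screen alone, which does not by itself show that the screens differ at them.

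The direct comparison of the sorted libraries, which does not use the control, tested that difference. Of 6138 genes, 3 held a higher share in the CD59 screen and 7 in the PrP screen. Higher in the CD59 screen were CD59 itself, PIGN and PIGO, enzymes that add ethanolamine phosphate to the mannoses of the anchor. PIGN held 0 insertions in the PrP screen where 21.5 would be expected at its CD59 share. Its share was thus at least 7.15-fold higher in the CD59 screen (exact lower limit of the odds ratio 5.71), with an adjusted p of 1.19e-05 by Fisher's exact test. PIGO had an odds ratio of 3.81 (1.94 to 8.54) and an adjusted p of 0.00384 by the same test. In the edgeR exact test with assumed variation PIGN passed between the screens with TMM factors (adjusted p 0.00585) and not without them (0.286), and PIGO passed in neither, with an adjusted p of 1. The call of PIGO in the PrP screen ended with TMM factors (0.414) and with sense intron insertions alone (0.761), and was kept without TMM factors (0.00792).

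Higher in the PrP screen were PRNP, SEC62, SEC63, PIGP, PIGS, GPAA1 and NLK. The odds ratio of SEC62 was 30.6 (7.27 to 274), with an adjusted p of 9.10e-07 by Fisher's exact test. The share of SEC63 was at least 14.3-fold higher (exact lower limit of the odds ratio 10), with an adjusted p of 1.19e-05 by the same test. In the edgeR exact test neither SEC62 nor SEC63 passed between the screens, with an adjusted p of 1 each with TMM factors and of 0.286 and 1 without. Against control SEC62 passed in both, and SEC63 passed without TMM factors (2.35e-05) and not with them (0.0594). PIGP, PIGS and GPAA1 were called in both screens and had odds ratios of 2.52 (2.03 to 3.13), 1.76 (1.43 to 2.15) and 2.15 (1.60 to 2.87) for PrP over CD59. With the TMM factors of edgeR these 3 genes lay on the other side, with log2 ratios of 0.15, 0.65 and 0.35 for CD59 over PrP and an adjusted p of 1 each by its exact test. Without TMM factors they were higher in PrP, again with an adjusted p of 1 each by that test. TMM factors use only genes with insertions in both libraries, and the PrP library held insertions in 1824 genes. The turn of direction thus came with the factors and may reflect that choice of genes. NLK, which encodes a protein kinase, held 9 insertions against 2, with 1653 in control, and was not called against control in the PrP screen, where its adjusted p was 0.169 by Fisher's exact test. When the insertions in the 19 shared genes were taken as the library total, PIGS, GPAA1 and NLK were no longer called among all genes.

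The other list members did not pass the direct test. Odds ratios for CD59 over PrP were 8.38 (1.39 to 342) for PGAP2, 3.92 (1.45 to 14.9) for MPDU1, 2.98 (0.931 to 15.2) for PIGX, 2.58 (0.927 to 9.99) for DPM1 and 1.66 (1 to 2.92) for PMM2. PIGF held 19 insertions against 0, a share at least 1.77-fold higher in the CD59 screen (exact lower limit of the odds ratio 1.30). In the other direction PIGC had an odds ratio of 2.83 (1.54 to 5.14) for PrP over CD59, with an adjusted p of 0.223 by Fisher's exact test. The lists for ethanolamine phosphate addition, the transamidase and ER translocation each held 2 genes called between the screens, and GlcNAc-PI synthesis with mannosylation held 1. In that order the random lists reached 2, 3, 2 and 4 called genes, and 99.6%, 98.4%, 99.8% and 59.9% of them held fewer than the list. Adjusted over the list alone the called members were 3, 3, 2 and 2, with 1 each for dolichol phosphate mannose supply and remodelling, which held none over all genes. The random lists were not well matched for members with many insertions. PIGS held the highest count of both sorted libraries, 312 and 150, so its replacements all held smaller shares. Genes with fewer insertions are less easily called, so the percentages of random lists do not decide whether these lists stand out between the screens.

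**Figure D2:**
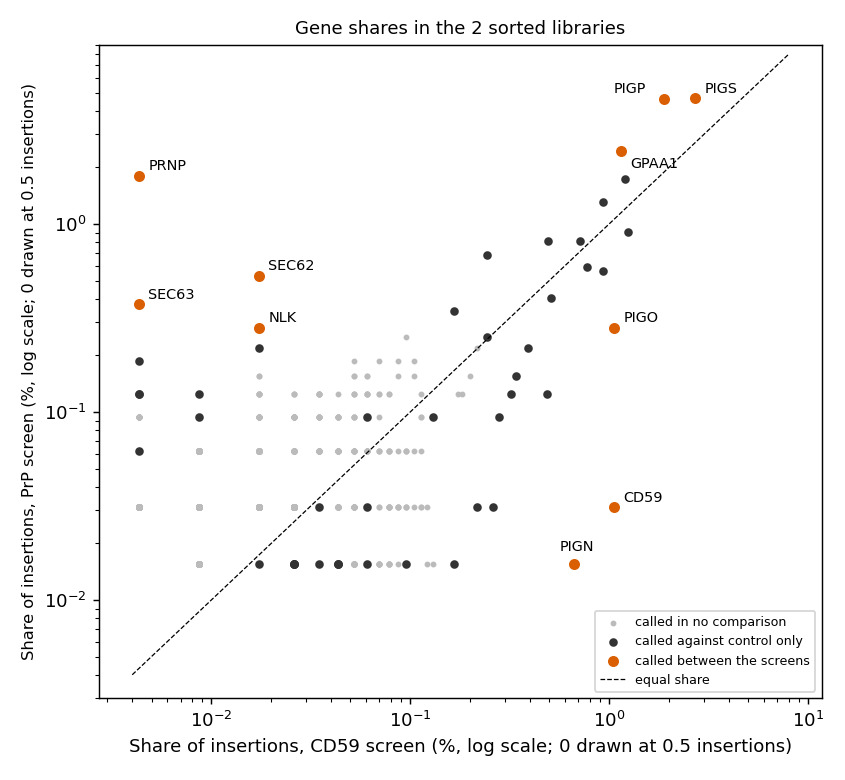
Each point is a gene with its share of inactivating insertions (percent, log axes) in the CD59 screen on the horizontal and the PrP screen on the vertical axis; a count of 0 is drawn at 0.5 insertions and the dashed line marks equal shares. The 10 genes called between the screens are orange and named, with PRNP, SEC62 and SEC63 far above the line and CD59 and PIGN far below it.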

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

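All tests in this part were chosen after the result was seen, except the direct comparison of the screens, the simulated libraries, edgeR with TMM factors and Bonferroni adjustment.

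The following genes had effects in the 2 screens that differed by the direct Fisher's exact test. Higher in the CD59 screen were CD59 with an odds ratio of 34.4, PIGO with 3.81 and PIGN, whose share was at least 7.15-fold higher (exact lower limit of the odds ratio 5.71). Higher in the PrP screen were SEC62 with an odds ratio of 30.6, NLK with 16.2, PIGP with 2.52, GPAA1 with 2.15 and PIGS with 1.76. The shares of PRNP and SEC63 were at least 69.4-fold and 14.3-fold higher there (exact lower limits of the odds ratio 55.6 and 10).

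The list members PIGN, PIGF, PGAP2, PIGX and MPDU1, and SPPL3, were called in the CD59 screen and not in the PrP screen, which holds fewer insertions. When the CD59 library was thinned to the PrP total, a median of 27 genes was called (22 to 32 over 1000 draws), and each of these 6 genes was still called in 83.3% to 100% of draws. The direct Fisher's exact test, adjusted over all genes tested between the screens, gave p = 1.19e-05 for PIGN, which argues against lower depth of the PrP library alone for this gene as far as counting error goes. In the edgeR exact test with assumed variation its adjusted p was 0.00585 with TMM factors and 0.286 without, so variation between libraries stays open. The direct Fisher's exact test gave an adjusted p of 0.927 for MPDU1 and 1 for PGAP2, PIGF, PIGX and SPPL3. Most thinned draws kept the calls of these genes too, which lower depth alone does not predict. They were picked by their CD59 calls, however, and held few PrP insertions, 4 at most. Lower depth of the PrP library is thus not settled for them. A difference between the proteins in what they need stays open for all 6 and was not tested beyond these libraries.

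PIGP, PIGS and GPAA1 took a larger share of the PrP library, which might reflect a larger share of low-staining mutants in that sort. Such a factor would move all shared genes alike, and it cancels when the insertions of the 19 shared genes are the total. The odds ratio of PIGP for PrP over CD59 was then 2.03 (1.60 to 2.57), against 2.52 with the whole library as total, with p of 5.21e-06 by Fisher's exact test adjusted over all genes tested, which argues against such a factor alone. For PIGS the odds ratio went from 1.76 (1.43 to 2.15) to 1.34 (1.07 to 1.68) and for GPAA1 from 2.15 (1.60 to 2.87) to 1.63 (1.20 to 2.21). Both intervals lie above 1, and adjusted over the 19 genes alone Fisher's exact test gave p of 0.0251 and 0.00595. Adjusted over all genes tested it gave 1 and 0.687, which ended the calls as the ratios fell. The outcome for these 2 genes thus depends on the genes adjusted over, and the factor stays open for each taken singly. With sense intron insertions alone and the whole library as total, the odds ratio was 1.80 (1.38 to 2.33) for PIGP and 1.73 (1.38 to 2.15) for PIGS, so exon insertions are not the whole of either difference. For PIGP that interval lies below the 2.52 of all inactivating insertions, so exon insertions make up part of its difference. For GPAA1 the value was 1.49 (0.917 to 2.37), which leaves this open. Sense intron insertions were not tested with the 19 shared genes as the total. The share of low-staining mutants and the exon insertions acting together thus stay open for PIGP. Repeated counting of a few sites cannot be examined without positions.

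Outside the lists, 14 genes other than CD59, PRNP and SPPL3 were called in the CD59 screen and 7 in the PrP screen, each with few insertions. Unchanged libraries of these totals called at most 1 gene in 200 simulations, at a stricter p than here because they held no changed gene. In the simulated libraries with 200 genes raised, a mean of 0.2 unchanged genes was called for each screen. This argues against counting error alone for the set. Genes with 0 control insertions, such as AK075337 in the PrP screen, could not be called in these simulations. The edgeR exact test with assumed variation ended all 14 and all 7 calls, with TMM factors and without them. For RUVBL1 the log2 ratio to control was 2.60 with an adjusted p of 0.845 with TMM factors, and 3.61 with 0.659 without. Bonferroni adjustment ended 10 of the 14 calls, and those of HDGF, MOXD1, PYGO1 and RUNDC3B among the 7. Without TMM factors edgeR uses the library totals as they are, so the factors did not end the calls there. Whether the assumed variation or another step of that test ended them was not tested. Variation between libraries beyond counting thus stays open. A control library that under-represents these genes would raise them in both screens. The genes of the PrP screen held 4 insertions in the CD59 library with 5.78 expected, a ratio of 0.692 (0.189 to 1.77), which argues against that for these genes pooled. HDGF and A1BG gave 2.99 and 1.22 of the expected insertions, MOXD1 gave 0.159 and AK075337 gave 0. The ratio thus cannot decide for genes with few control insertions. The genes of the CD59 screen held 5 in the PrP library with 1.05 expected, a ratio of 4.76 (1.55 to 11.1), and 2.22 (0.268 to 8) without CCDC102B. Under-representation in control stays open for them.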

How the results depend on the processing

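The count of 40 genes in the CD59 screen lay between 30 and 47, and that of 29 in the PrP screen between 24 and 36, under the planned settings other than edgeR and with sense intron insertions alone; the authors' deposited table of p-values, adjusted over the same genes, gave 44 and 31. The edgeR exact test with assumed variation called 23 and 14 genes higher and 0 and 4 lower, and between the screens 2 genes higher in CD59 and 1 higher in PrP. TMM factors differed 2.02-fold and 4.99-fold from control in the sorted libraries. Such factors use only genes with insertions in both libraries compared, which leaves out most genes with insertions in control. Results that turn on them are therefore uncertain. In the edgeR exact test with assumed variation, without TMM factors, 26 and 17 genes were higher and 0 lower, and between the screens 0 were higher in CD59 and 1, PRNP, in PrP. The counts thus fell without TMM factors too, and whether the assumed variation or another step of that test lowered them was not tested. With them, SEC63, PIGO, PIGV, PIGW, PIGL, PIGM, PIGA and DPM1 were lost from the PrP screen, PGAP2, PIGL and PIGW from the CD59 screen, all called genes outside the lists other than CD59, PRNP and SPPL3 from their screens, and between the screens CD59, PRNP and PIGN passed. With the library total of genes called in both screens, 4 genes were higher in PrP, in place of 7, because PIGS, GPAA1 and NLK did not pass. In the settings other than these the number higher in PrP lay between 6 and 10. Bonferroni adjustment lost NLK between the screens and PIGA from the PrP screen, and sense intron insertions alone lost GPAA1 between the screens and PIGO from the PrP screen. The direction turned for PIGP, PIGS and GPAA1 between the screens in the edgeR exact test with assumed variation, with an adjusted p of 1 each, and for SPIN2B, CXorf40B and AX747770 in the CD59 screen with sense intron insertions only, of which they hold 0, also with an adjusted p of 1. The overlap was 18 genes at a threshold of 0.001, against 19, and in the edgeR exact test with assumed variation 12 with TMM factors and 14 without. With all genes and without called genes in the total, the log2 odds ratio of CD59 between the screens was 5.10 and 4.98, and the log2 of the least fold of PRNP was 6.12 and 6.19. The number of lists whose median lay above the 95th percentile was 5 for CD59 in all settings, and 5 for PrP, with 4 or 6 in the alternatives. The members changed: with pseudocount 1 the ribosomal proteins fell from 97.3 to 89.5 in the CD59 screen and the ER membrane protein complex rose from 93.7 to 97.2. In the PrP screen matched on the mean, the side chain and oligosaccharyltransferase lists fell to 50.7 and 67.7 and ER translocation rose from 77.6 to 99. Sense intron insertions alone, the total of genes called in both screens, the deposited p-values, edgeR without TMM factors and its overlaps were chosen after seeing the data, and counts of all insertions were not run. No paired analysis was possible because each group holds 1 library. Depth limits the PrP screen most, since a gene with 50 control insertions needed 4 insertions, a 63.3-fold enrichment, for a call.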

Other observations

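Tests in this part were chosen after the counts were seen, except those of the further ribosomal protein genes and the proteasome, which were chosen before their counts were seen, and edgeR with TMM factors and pseudocount 1, which were chosen before the data were seen.

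Insertions were compared between steps of the GPI pathway in the 2 sorted libraries. The 23 genes used are the list members called in the CD59 screen other than PGAP2, and the 3 groups joined below were chosen because they ran the same way, so their joint ratios describe these libraries and test nothing. Among the insertions in these genes, the mannose donor, mannosyltransferase and ethanolamine phosphate genes together took 39.8% (37.6% to 42.0%) in the CD59 library and 15.2% (12.6% to 18.2%) in the PrP library, an odds ratio of 3.67 (2.92 to 4.66). It was 3.00 (2.35 to 3.85) without PIGN and PIGO, 3.01 (2.37 to 3.86) in the 19 genes called in both screens, 2.64 (2.05 to 3.43) in these without PIGO, and 3.71 (2.94 to 4.70) in all 35 list members, called or not. Taken one by one the odds ratios for CD59 over PrP were 9.34 (4.79 to 20.8) for ethanolamine phosphate addition, 2.51 (1.76 to 3.65) for mannose donor supply and 2.05 (1.51 to 2.82) for the mannosyltransferases PIGM, PIGX, PIGV and PIGB. In the other direction, GlcNAc-PI synthesis with inositol acylation had an odds ratio of 1.88 (1.54 to 2.28) for PrP over CD59, which was 1.36 (1.01 to 1.83) without PIGP, and the transamidase had 1.65 (1.38 to 1.97). Shares within a library depend on each other, so a gain in some groups lowers the rest.

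Across the 19 shared genes, 11 differed between the screens when their insertions were taken as the total and Fisher's exact test was adjusted over these 19 genes alone. PIGO, PMM2, PIGB, PIGV, PIGL, PIGM and DPM1 were higher in the CD59 library and PIGP, PIGC, GPAA1 and PIGS in the PrP library. In 100000 random reassignments of the insertions to the screens, none was as uneven, with a permutation p of 1e-05, the smallest they can give. A single factor for the purity of the sorts moves all 19 genes alike and cannot give this spread over the set, which does not settle it for PIGS and GPAA1 taken singly. The permutation takes insertions as independent and covers counting error only. None of these 11 genes passed between the screens in the edgeR exact test with assumed variation, with or without TMM factors, so variation between libraries stays open. A difference between the proteins in what they need, and differences between the mutagenized pools, were not tested.

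Insertions in exons were less frequent among the CD59 library's insertions than among the control's in 8 of 44 called genes tested, after adjustment of Fisher's exact test, and in none of 36 for the PrP library. The PrP tests rest on fewer insertions, so this difference in number may reflect depth. In PIGS the exon share was 16.0% in the PrP library and 28.4% in control, with an adjusted p of 0.261 by Fisher's exact test. Between the screens PIGP and PIGV differed. Of the insertions in PIGP, 11.9% lay in exons in the CD59 library, 38.3% in the PrP library and 40.9% in control. For PIGV the values were 6.74%, 42.1% and 49.7%. Over all genes the share was 16.7%, 19.2% and 18.2%.

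The list of 40 cytosolic ribosomal proteins held 24 insertions in the CD59 library with 11.4 expected, a ratio of 2.10 (1.35 to 3.13), with 6 in RPL4 and 5 in RPL9, and 1 in the PrP library with 3.18 expected. Without RPL4 and RPL9 the ratio was 1.57 (0.835 to 2.68), and the median of the list was not above the 95th percentile with pseudocount 1. The hypothesis that insertions in genes needed by dividing cells are over-represented in the CD59 library was tested on other genes. A further 37 ribosomal protein genes had a ratio of 0.726 (0.332 to 1.38) and 31 proteasome genes had 0.919 (0.397 to 1.81), neither of which bears it out.

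RUVBL1, named after its values were seen, held 11 insertions in the CD59 library with 0.898 expected, an odds ratio of 12.3 (6.02 to 22.4), and 0 in the PrP library. The edgeR exact test with TMM factors gave it an adjusted p of 0.845. SPIN2B and CXorf40B held 3 insertions each in the CD59 library, all in exons. RefSeq lists a gene of the same family for each, SPIN2A and CXorf40A, on the same chromosome, and whether reads can be placed between them was not examined.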
